A study of Mus musculus with 7 samples.

How the data were processed

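Adenine methylation left by CHD8-Dam or by Dam alone was profiled by Targeted DamID sequencing in cortex of MF1 mouse embryos. The plasmids (0.5 µg/µl of the CHD8-Dam or Dam-only construct with 0.25 µg/µl of an electroporation control) were delivered to the brain ventricles on embryonic day 13.5, and cortex was taken on embryonic day 17.5. Per the labels, genomic DNA was digested with DpnI, which acts at methylated GATC sites, ligated to adaptors, digested with DpnII, which acts at unmethylated GATC sites, amplified, sonicated and sequenced as 50 bp reads. The labels give 4 CHD8-Dam and 3 Dam-only libraries, and samples were grouped by construct from these labels.

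Per the submitters' processing notes, the tools were Trim Galore 0.4.2, FastQC 0.11.9, BWA 0.7.17, SAMtools 1.10, MACS2 2.2.5, bedtools, deepTools 3.3.1 and HOMER, with builds mm10 and GRCm38; their settings are not given in the sources used here. The deposited files are MACS2 broad peak lists, 1 per library, a list of peaks from the pooled Dam-only libraries (merged Dam-only peaks below) and a list of merged CHD8-Dam regions. The fold of each peak is, per the file names and format, the authors' own ratio over the background that MACS2 used. Each CHD8-Dam list was called against the pooled Dam-only libraries, whereas no control library is named for the Dam-only lists, so both kinds of list were made differently. The other deposited value used here is the authors' -log10 q of each peak, which is a -log10 p adjusted by MACS2. The last column of the authors' merged list equalled the number of CHD8-Dam lists with a peak of -log10 q of at least 5 over the region in all 6268 regions on chromosomes 1 to 19 and X, so each merged region rests on 3 or 4 of the replicates. Peak lists hold no counts: the depth per sample is unknown, and no interval that needs it is given. The folds served only to describe, rank and filter peaks.

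Peaks and regions on chromosomes 1 to 19 and X were joined by coordinates to 21627 protein-coding genes of the GRCm38 annotation. The planned windows around transcription start sites became windows of 2 kb on each side of either end of a gene, because the gene table used here gives no strand. A region was placed in the first class that held: at a gene end, inside a gene, intergenic within 10 kb of an end, or intergenic beyond 10 kb. A gene counted as bound when a merged CHD8-Dam region overlapped a window at either end by at least 1 bp. Gene lists (24 in all) and 13 single genes were fixed before the data were examined, and of 2264 listed symbols 1 had no gene in the table.

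Overlaps were compared with 100 random placements of the peaks on their own chromosome, between the lowest start and the highest end of the deposited peaks (2569.89 Mb in all), in one-sided tests whose smallest possible p is 0.0099. Shares per library were compared between constructs by a two-sided exact permutation test over 35 splits, whose smallest possible p is 0.0571. Gene lists were tested by a two-sided Fisher's exact test against all other genes, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. The same test was run on genes with merged Dam-only peaks. Log2 odds ratios were computed with 0.5 added to each count, so those of lists with 0 bound genes depend on this value. The log2 odds ratio of each list was also computed from each library's own peaks, as mean and SD over replicates. Genes are not independent replicates, since neighbouring genes can share a region and the Hox genes lie in clusters.

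Regions were ranked by the number of CHD8-Dam lists with a peak over them, then by the mean log2 fold of the highest peak in each of these lists. The genes named by a rule fixed before the data were examined are those at an end of the 15 top-ranked regions that have one, the nearest gene of the 5 top-ranked regions beyond 10 kb of any end, up to 4 top-ranked members of each gene list, the 13 fixed genes, and the 5 genes with the highest mean Dam-only fold at an end. Not every gene so named is printed, and some results on single genes are not reported here.

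The tests were tried on simulated data. For the gene lists, simulated genes were bound independently of each other and lists were drawn at random. The rates below may therefore not hold where neighbouring genes share a region. Gene lists without an effect were called in 0.104% of tests, and an odds ratio of 4 planted in a list of 45 genes was called in 90.5% of 200 runs with a mean log2 odds ratio of 1.92 where the true value was 2. A planted overlap of 25% was measured as 25.4%. Alternatives tried include stricter peaks, equal numbers of peaks per library, other windows and overlaps, a background of genes with merged Dam-only peaks, and leaving out each replicate. Motif, GATC, CpG and GC content were not analysed here, and neither were exons and introns, since no genome sequence or transcript models were used. Peaks on the Y chromosome and mitochondrial DNA were left out of the comparisons. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.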

Results

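Targeted DamID was used to ask where CHD8, a chromatin remodelling ATPase whose gene is among those most often mutated in autism, contacts the genome in the fetal mouse cortex. In this assay a protein is fused to the bacterial Dam methylase, which methylates adenine in GATC sites near the places that the fusion visits. Dam expressed alone marks accessible chromatin and gives the background. The series held 4 CHD8-Dam and 3 Dam-only libraries from embryonic cortex. The CHD8-Dam replicates 1 to 4 had 21105, 35650, 89681 and 246772 deposited peaks. The Dam-only replicates 1 to 3 had 39615, 55321 and 64415. The depth behind these lists is unknown. Nothing in the labels says that replicates came from separate animals, so p-values between libraries measure only the spread between these samples, which may be technical.

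The first question was where in the genome CHD8-Dam methylation exceeded that of Dam alone. The authors' merged list held 6268 regions on chromosomes 1 to 19 and X, with a median width of 827 bp. Most lay at ends of protein-coding genes. Within 2 kb of a gene end lay 4402 regions (70.2%), against 7.28% of randomly placed regions (9.65 times as many, one-sided permutation p over placements = 0.0099, the smallest possible). Inside genes, more than 2 kb from an end, lay 1067 regions (17%, against 37.0% placed). A further 637 (10.2%, against 48.6% placed) were intergenic and more than 10 kb from any gene end. A total of 4559 of 21627 protein-coding genes (21.1%) had a region at an end, 315 of them at both ends. In the replicates' own lists the share at gene ends was 30.1% ± 23.6 (SD, n = 4), and no single list reached the share of the merged regions.

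Of the named regions at gene ends, the one at Ppp2ca, which encodes a catalytic subunit of protein phosphatase 2A (chromosome 11, 52098015 to 52099139, over the lower end of the gene), ranked highest, with a mean log2 fold over pooled Dam-only of 3.90 ± 0.20 (SD, n = 4). The region at an end of Dok2, which also overlaps Xpo7 (chromosome 14, 70765834 to 70767188), had 3.70 ± 0.29. The region at the palmitoyltransferase gene Zdhhc5 (chromosome 2, 84714204 to 84716229) had 3.64 ± 0.32. At genes of chromatin factors the values were 3.50 ± 0.21 for Srcap (chromosome 7, 127511622 to 127513207) and 3.43 ± 0.35 for Arid2 (chromosome 15, 96283365 to 96286476). The other 10 of these 15 regions lay at Fbxo28, Vash2, Ado, Rhoq, Zc3h4, Tmem165, Xndc1 and Xntrpc, Add1, Ttc7b, and Cpt1c and Prmt1, with means from 3.43 to 3.61. More than 10 kb from any gene end, the highest regions lay inside Phf14 (3.61 ± 0.17), the neuronal membrane glycoprotein gene Gpm6a (3.48 ± 0.45), Chd8 itself (3.32 ± 0.64) and the synaptic scaffold gene Magi2 (3.32 ± 0.51). The fifth of these (3.25 ± 0.36; chromosome 16, 77643801 to 77645111) was intergenic, with Usp25 as the nearest gene at 527017 bp. These folds are the authors' values per peak.

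**Figure D1:**
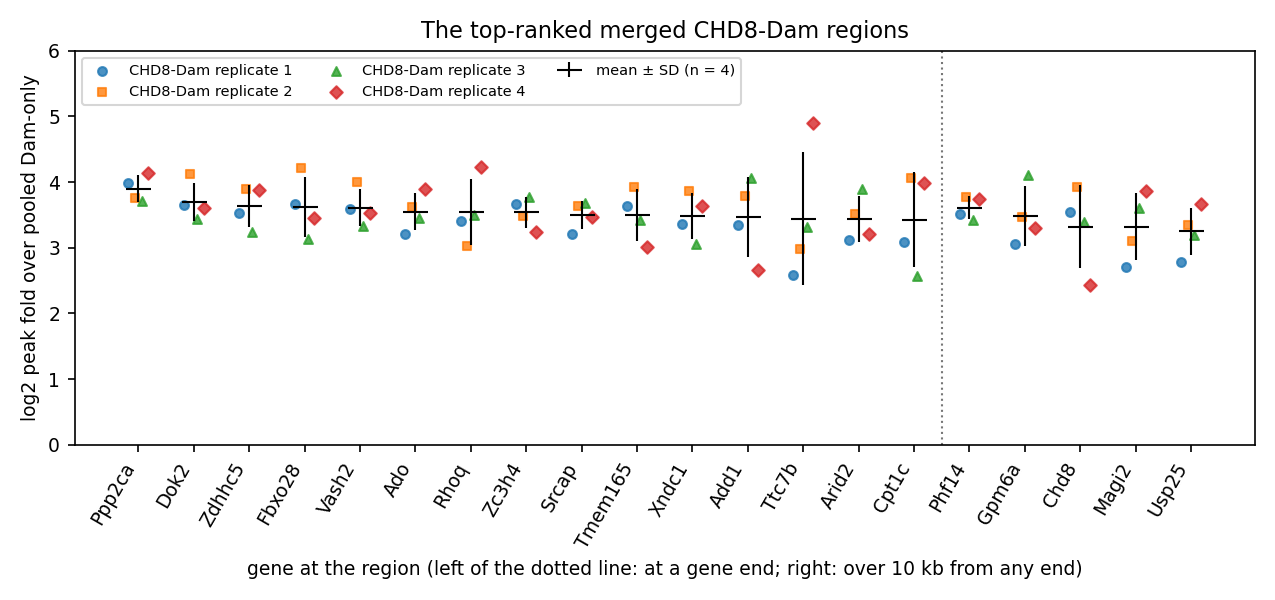
Log2 fold of the highest peak over each top-ranked merged CHD8-Dam region, for each of the 4 CHD8-Dam replicates (coloured symbols) with mean and SD (black), for 15 regions at gene ends and 5 regions more than 10 kb from any gene end. The means lie between 3.25 at the region nearest Usp25 and 3.90 at Ppp2ca, and replicate 4 stands far above the others at Ttc7b.

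The second question was which groups of genes carried CHD8-Dam regions. Of 24 gene lists fixed in advance, 13 had regions at a larger share of their genes than all other genes did, 5 at a smaller share, and 6 did not pass the test. The test was a two-sided Fisher's exact test with adjustment over the lists. RNA processing genes were highest, with 33 of 45 bound (odds ratio 10.4, 95% interval 5.21 to 22.1, exact adjusted p = 1.0e-12). Among them were Ddx5, an RNA helicase gene (mean log2 fold 3.22 ± 0.73, n = 4), and Hnrnpa2b1 (3.01 ± 0.21). Ribosomal protein genes were also bound more often (27 of 50, odds ratio 4.41, exact adjusted p = 1.5e-06), such as Rpl32 (3.10 ± 0.28). So were mitochondrial respiratory chain genes (18 of 37, odds ratio 3.56, exact adjusted p = 0.00047), such as Ndufv2 (3.10 ± 0.36). Chromatin regulators (31 of 58, odds ratio 4.32, exact adjusted p = 3.5e-07) included Ep300, a histone acetyltransferase gene (3.00 ± 0.40), and Smarcb1, a core subunit gene of BAF complexes (2.89 ± 0.36). Of 54 autism risk genes 28 were bound (odds ratio 4.05, exact adjusted p = 2.3e-06), with Phf21a (3.28 ± 0.56), Kmt5b (3.20 ± 0.20) and Arid1b (3.07 ± 0.62). Of 30 genes of the p53 pathway 12 were bound (odds ratio 2.5, exact adjusted p = 0.030), among them Mdm2 (2.79 ± 0.74) and Trp53 (2.64 ± 0.11).

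Genes of the excitatory cortical lineage were bound from progenitors to neurons. Pan-neuronal genes had the highest share among the cell type lists, with 23 of 35 (odds ratio 7.21, exact adjusted p = 1.2e-07). They included Stmn2 (3.10 ± 0.33), which encodes a regulator of microtubules, and Dcx on the X chromosome (2.96 ± 0.18), a marker of migrating neurons. Markers of radial glia and apical progenitors were also bound more often (17 of 30, odds ratio 4.91, exact adjusted p = 6.4e-05), with Id4 (2.86 ± 0.53), Lhx2 (2.75 ± 0.51) and Sox2 (2.60 ± 0.17). So were those of intermediate progenitors (9 of 18, odds ratio 3.75, exact adjusted p = 0.012), with the proneural gene Neurog2 (2.74 ± 0.17) and Sox4 (2.67 ± 0.41). Upper-layer projection neuron genes (12 of 22, odds ratio 4.50, exact adjusted p = 0.0013), such as Cux1 (2.94 ± 0.34), and deep-layer genes (9 of 20, odds ratio 3.07, adjusted p = 0.030), such as Etv1 (2.94 ± 0.42) and Fezf2 (2.30 ± 0.45), were both bound more often than other genes. The difference between the upper-layer and deep-layer lists did not pass Fisher's exact test (adjusted p = 0.76 over 6 pairs of lists). Each other pair passed (adjusted p of 1.2e-06 to 6.3e-05), such as pan-neuronal against GABAergic genes. All 6 pairs were chosen after their values were seen, which favours low values. Axon guidance genes (24 of 44, odds ratio 4.51, exact adjusted p = 3.9e-06) included Sema7a (2.96 ± 0.58) and Dcc, a netrin receptor gene (2.93 ± 0.32). Genes of synaptic adhesion and scaffolds (16 of 42, odds ratio 2.31, exact adjusted p = 0.021) included Grin2b (3.05 ± 0.46) and Adgrl3 (3.01 ± 0.35). For each of these 13 lists the log2 odds ratio was above 0 in 4 of 4 replicates' own lists, for example 3.12 ± 0.56 (SD, n = 4) for RNA processing and 2.60 ± 0.89 for pan-neuronal genes. The merged regions rest on these same replicates, so this is not independent support. It does not set the 13 lists apart either, since Wnt signalling and cell cycle genes, which did not pass the test, were also above 0 in 4 of 4.

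Within 2 kb of a gene end, some lists of other cell types had few or no regions. Only Cxcr4, a chemokine receptor gene, was bound among 28 genes of GABAergic interneurons (odds ratio 0.138, exact adjusted p = 0.030). Dlx1, Dlx2, Gad1, Gad2 and Lhx6, known regulators or markers of these cells, were not bound. No region lay at 22 genes of the oligodendrocyte lineage (exact adjusted p = 0.015), at 19 erythroid genes (adjusted p = 0.030) or at 39 Hox genes (adjusted p = 0.00051). Of 1459 olfactory and vomeronasal receptor genes 1 had a region, Vmn1r4, and this region overlapped Nt5c3 (exact adjusted p = 1.6e-152). Astrocyte genes (1 of 24, Sox9, exact adjusted p = 0.052), microglial genes (2 of 25, Sall1 and Irf8, adjusted p = 0.15), endothelial and pericyte genes (3 of 29, adjusted p = 0.26) and genes of liver, muscle and skin (4 of 40, adjusted p = 0.13) did not pass the test. The same held for Wnt signalling (15 of 44, exact adjusted p = 0.052), with Gsk3b (2.92 ± 0.34) highest, and for cell cycle and DNA replication (12 of 46, adjusted p = 0.37), with Rbl1 (2.95 ± 0.60) highest. In the replicates' own lists the GABAergic genes were closer to other genes than in the merged regions (log2 odds ratio -0.87 ± 0.75, n = 4, against -2.29). Astrocyte genes were near other genes in these lists (-0.10 ± 0.38), and within 5 kb of an end or over the gene body 5 of 24 had a merged region (log2 odds ratio -0.16 and 0.06).

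**Figure D2:**
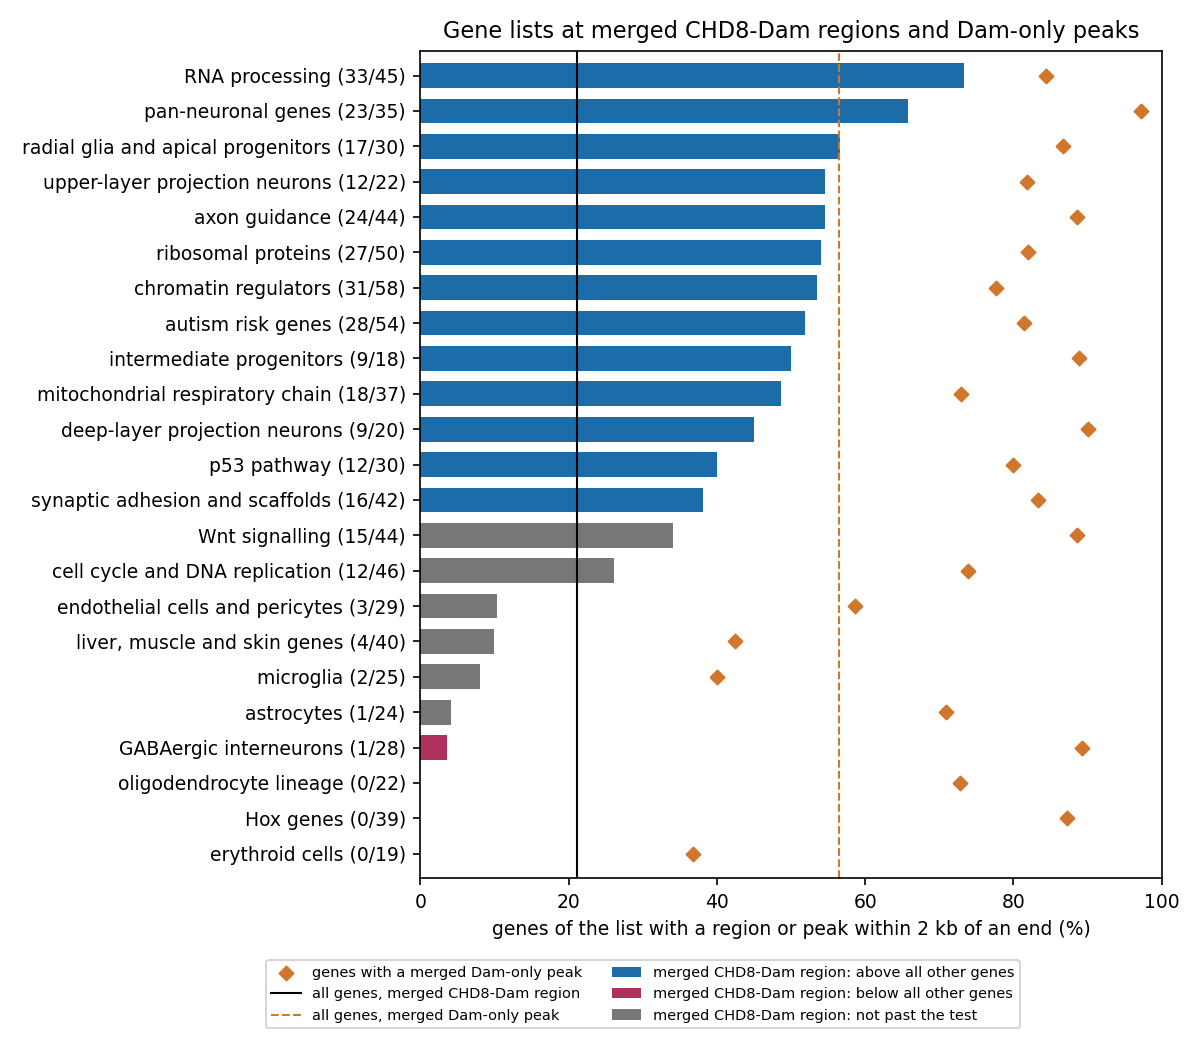
Share of each gene list with a merged CHD8-Dam region within 2 kb of a gene end (bars, with bound and tested genes in parentheses) and with a merged Dam-only peak there (diamonds), for 23 lists without the olfactory and vomeronasal receptors, with lines at the shares over all genes, 21.1% and 56.4%. RNA processing (33 of 45) and pan-neuronal genes (23 of 35) are highest, and the lists without a bar (oligodendrocyte lineage, Hox genes and erythroid cells, with 0 bound genes) were below all other genes.

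Some of these calls ended under other choices. With 1 replicate left out and a peak required in each of the other 3, leaving out replicate 1, 2 or 4 gave 3081, 3038 and 3155 bound genes instead of 4559. Each of these 3 cases requires a peak in replicate 3, which had none in 1998 merged regions. The same 6 calls ended in each case. Their log2 odds ratios were 1.15 to 1.21 for the p53 pathway (1.34 with all regions; exact adjusted p 0.094 to 0.10), 1.39 to 1.46 for deep-layer neurons (1.63; 0.088 to 0.10) and 1.1 to 1.16 for synaptic genes (1.22; 0.075 to 0.084). For GABAergic interneurons they were -1.65 to -1.58 (-2.29; 0.14 to 0.20), with 1 gene bound as before. The oligodendrocyte lineage (0.094 to 0.10) and erythroid cells (0.14 in each case) still had 0 bound genes, and only the share of other genes had fallen. Leaving out replicate 3 gave 4415 bound genes, ended no call and added Wnt signalling (0.047). Windows of 1 or 5 kb and whole gene bodies also ended the p53 pathway's call (0.055 to 0.079) and brought Wnt signalling past the threshold (0.013 to 0.045). Windows of 5 kb ended the call of erythroid cells (0.29), and whole gene bodies added the genes of liver, muscle and skin on the low side (0.041). Counting each region only for the nearest gene end ended the call of GABAergic interneurons (0.060) and added Wnt signalling (0.014).

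Among the 13 fixed genes, regions at an end were present at Chd8, Chd7, Chd2, Adnp, Arid1b, Ctnnb1 and Trp53. Of these, the beta-catenin gene Ctnnb1 (chromosome 9, 120934185 to 120935260) had a mean log2 fold of 2.2 ± 0.23 (n = 4) and Chd7 (chromosome 4, 8691734 to 8692508) had 2.46 ± 0.32. The cortical transcription factor genes Bcl11a and Tbr1 had 4 and 3 regions inside the gene and none at an end. In Bcl11a the region 2606 bp from the lower end (chromosome 11, 24079170 to 24079857) had 2.78 ± 0.24 (n = 4). Dyrk1a, Pogz and Olig2 had no merged region. In the replicates' own lists, however, Dyrk1a had a peak at an end in 3 of 4 CHD8-Dam lists and in 0 Dam-only lists. The pooled Dam-only libraries did give a merged Dam-only peak at an end of Dyrk1a (fold 3.29). For both Bcl11a and Tbr1 a peak at an end was present in 3 CHD8-Dam and 2 Dam-only lists. For Pogz it was present in 1 and 0, and for Olig2 in 0 and 1. Chd8 had 6 regions, of which 1 lay at its higher end (chromosome 14, 52257526 to 52258270, 2.47 ± 0.38 over 3 replicates). The others were narrow, at 213 to 394 bp, lay inside the gene and had no overlap with merged Dam-only peaks. The CHD8-Dam plasmid carries a CHD8 coding sequence, so peaks in this gene can include plasmid reads.

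**Figure D3:**
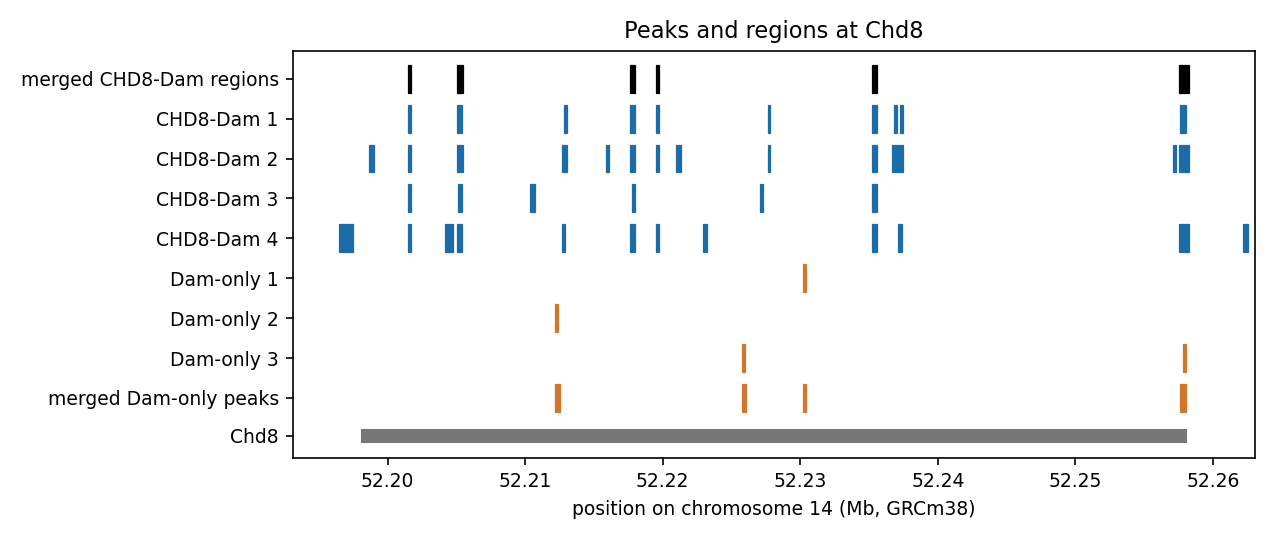
Peaks and regions along Chd8 on chromosome 14 (position in Mb, GRCm38), with 1 line for the merged CHD8-Dam regions, for each library, for the merged Dam-only peaks and for the gene. The 5 narrow regions inside the gene have peaks in 3 or 4 of the CHD8-Dam replicates and in none of the 3 Dam-only replicates, and the sixth region lies at the higher end of the gene.

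The third question was how far CHD8-Dam regions lay in chromatin that Dam alone marks. Of the merged regions, 69.2% overlapped a merged Dam-only peak, against 6.57% of placed regions (10.5 times as many, one-sided permutation p over placements = 0.0099, the smallest possible). Of the 4559 genes with a region at an end, 4190 (91.9%) also had a merged Dam-only peak within 2 kb of an end. This peak need not overlap the region or lie at the same end. Of the 12201 genes with a Dam-only peak at an end, 34.3% had a region. The genes with the highest Dam-only fold at an end were Brox (mean log2 fold 3.17 ± 0.11, SD, n = 3), the muscarinic receptor gene Chrm2 (3.12 ± 0.08), the neighbours Rida and Pop1 (3.01 ± 0.21) and Chchd2 (3.00 ± 0.25), of which Brox and Chchd2 also had a CHD8-Dam region. When peaks in all 3 Dam-only replicates were required the overlap was 24.7%. With 1 Dam-only replicate left out and peaks in both others required it was 30.2, 37.1 and 26.0% without replicates 1, 2 and 3.

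Dam-only peaks were frequent at gene groups with and without CHD8-Dam regions. Of the 24 lists, 16 had merged Dam-only peaks at more of their genes than all other genes (two-sided Fisher's exact test). They included lists with few or no CHD8-Dam regions, such as the Hox genes (34 of 39, exact adjusted p = 0.00030) and GABAergic interneuron genes (25 of 28, adjusted p = 0.00087). The others were the 13 lists above except the mitochondrial respiratory chain (27 of 37, exact adjusted p = 0.062), with Wnt signalling and cell cycle genes in addition. Olfactory and vomeronasal receptors were low (10 of 1459), and oligodendrocyte (16 of 22), astrocyte (17 of 24), microglial, endothelial, erythroid and liver, muscle and skin genes did not pass the test. Among genes with a merged Dam-only peak alone, 9 lists still had more CHD8-Dam regions (RNA processing, pan-neuronal, chromatin regulators, axon guidance, ribosomal proteins, autism risk, mitochondrial respiratory chain, radial glia and upper-layer neurons) and 4 had fewer (Hox, GABAergic interneuron, oligodendrocyte and astrocyte genes). Against this background 6 lists no longer passed. Their log2 odds ratios were 0.71 for the p53 pathway (1.34 against all genes; exact adjusted p = 0.34), 1.28 for intermediate progenitors (1.91; 0.18), 0.94 for deep-layer neurons (1.63; 0.27) and 0.37 for synaptic genes (1.22; 0.52). Few genes were left of erythroid cells (0 of 7 bound, exact adjusted p = 0.18) and olfactory receptors (1 of 10, 0.25). Among the 4328 genes with a peak in all 3 Dam-only replicates, a background chosen after seeing the data that left at most 20 genes per list, RNA processing passed the test on the high side (12 of 14, exact adjusted p = 0.046), and GABAergic (0 of 11, 0.025), oligodendrocyte (0 of 8, 0.048) and Hox genes (0 of 10, 0.025) on the low side. Ribosomal protein (9 of 11, log2 odds ratio 2.04, exact adjusted p = 0.13), pan-neuronal (12 of 15, 1.95, 0.085) and autism risk genes (12 of 16, 1.59, 0.15) did not pass, with few genes left. The Dam-only calls themselves also changed when such peaks were required: those of Hox and GABAergic genes ended (exact adjusted p = 0.44 and 0.0504), 5 lists remained high (p53 pathway, radial glia, pan-neuronal, synaptic and axon guidance genes) and 2 were low (olfactory receptors and microglia).

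The share of peaks at gene ends differed more among CHD8-Dam replicates than between constructs. Peaks within 2 kb of a gene end made up 53.5, 47.4, 10.1 and 9.47% of the CHD8-Dam lists 1 to 4 and 18.4, 16.6 and 16.0% of the Dam-only lists. The means, 30.1% ± 23.6 (SD, n = 4) and 17% ± 1.24 (SD, n = 3), differed by 13.1 percentage points, less than the spread between the CHD8-Dam replicates (two-sided exact permutation p = 0.571, smallest possible 0.0571). Without CHD8-Dam replicate 1, 2, 3 or 4 the difference was 5.34, 7.36, 19.8 and 20.0 points. The X chromosome held 5.0% ± 2.21 of CHD8-Dam peaks (n = 4) and 1.21% ± 0.347 of Dam-only peaks (n = 3, exact permutation p = 0.0571, the smallest possible), against 6.52% of the sequence compared. In CHD8-Dam replicates 1 to 4 it held 3.03, 3.17, 7.25 and 6.56%, so replicates 3 and 4 were near the share of the sequence and account for much of the difference in means. The CHD8-Dam lists were called against the pooled Dam-only libraries, whereas no control is named for the Dam-only lists, so these shares describe the lists.

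**Figure D4:**
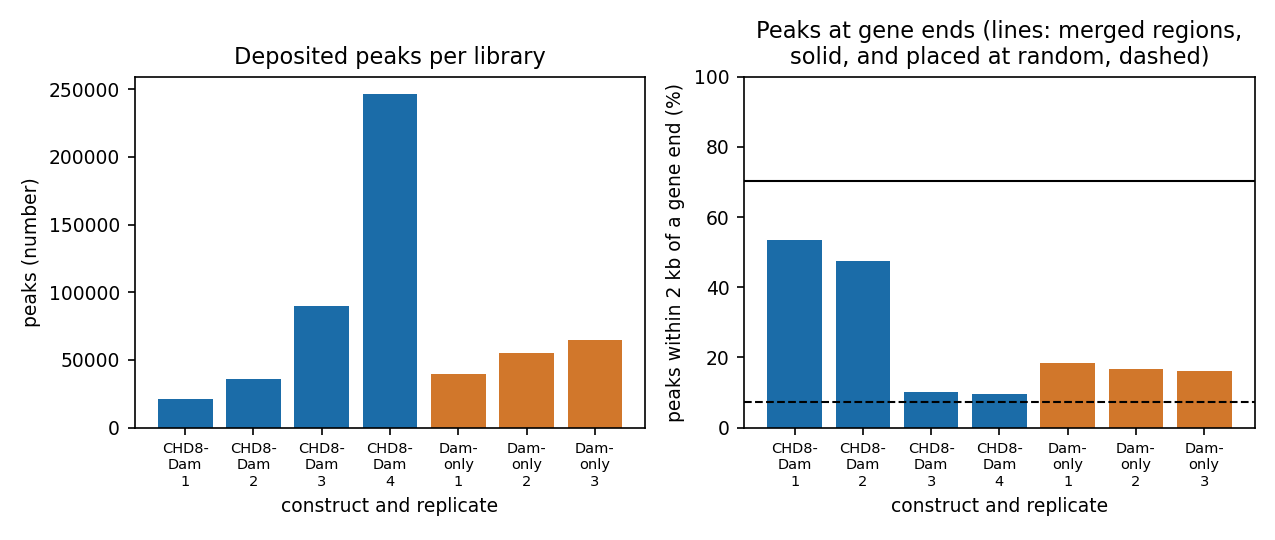
Number of deposited peaks per library (left) and the percentage of each library's peaks within 2 kb of a gene end (right), with CHD8-Dam in blue, Dam-only in orange, a solid line at the share of merged CHD8-Dam regions (70.2%) and a dashed line at that of placed regions (7.28%). The shares of CHD8-Dam replicates 1 and 2 (53.5 and 47.4%) lie above the Dam-only lists and those of replicates 3 and 4 (10.1 and 9.47%) below.

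Replicates of a construct shared more peaks than placed peaks did. Over the 6 pairs of CHD8-Dam lists, a mean of 48.9% of the shorter list's peaks overlapped the other list (28.3 to 77.9%), which was 3.97 to 72.4 times the share of placed peaks. Over the 3 Dam-only pairs it was 42.8% (31.5 to 63.7%), or 21.4 to 39.8 times (one-sided permutation p over placements = 0.0099 for each pair, the smallest possible). When CHD8-Dam peaks were placed only in the union of Dam-only peaks, the ratios fell to 1.53 to 7.42, and without replicate 1 or 2 the highest ratio over the genome was 10.9 or 15.7. Since all CHD8-Dam lists share the pooled Dam-only control, part of their overlap may come from it, and without counts this was not simulated. Of the merged regions 3928 had a peak in all 4 CHD8-Dam replicates and 2340 in 3. Replicate 3 had no peak in 1998 regions, replicate 4 in 190, replicate 1 in 147 and replicate 2 in 5. Thus 5926 regions had a peak in each of the replicates other than replicate 3, and 3933 to 4118 in each of the others when replicate 1, 2 or 4 was left out. With peaks of -log10 q of at least 5, 2029 regions had a peak in all 4.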

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

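The comparison at equal numbers of peaks below was chosen after its result was seen.

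Of 142 values over the 4 CHD8-Dam replicates, 8 had 1 replicate far from the others, where chance gives about 7.1 (1 in 20). Replicate 4 had 84428 peaks of -log10 q of at least 5, against 18216 in the next list. On the Y chromosome replicate 2 had 17 peaks, replicate 4 had 2, and no Dam-only list had more than 1. For the autism risk genes replicate 1 had a log2 odds ratio of 1.99, below 2.39 to 2.42 in the others, and for deep-layer neurons replicate 3 had 0.90, below 1.57 to 1.65. Among the named regions, replicate 4 had a fold of 29.7 at Ttc7b and 15.9 at Arid1b, and replicate 2 had 6.12 at Sox9 and 10.7 at Mfsd2a, each above the other replicates. In mitochondrial DNA a merged region (143 to 1712) had a peak in 4 of 4 CHD8-Dam lists and in 0 of 3 Dam-only lists, with folds up to 7.76.

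The share of peaks at gene ends ranged over 44.0 percentage points among the 4 CHD8-Dam lists. The length of the lists as the whole cause is argued against by a range of 38.6 points at equal numbers of peaks, where the Dam-only lists ranged over 1.11. Background spread at random stays open: peaks away from gene ends were shared 3.90 (replicates 3 and 4) to 123 times (1 and 2) as often as placed peaks, above the 1.5 times set before, but all lists share 1 control, which could make background peaks coincide and was not simulated, so that bound was wrong. Peaks away from gene ends lay in merged Dam-only peaks in 41.0, 42.2, 2.81 and 5.43% of cases in replicates 1 to 4, which is 10.9, 10.6, 0.806 and 1.35 times the placed share. On the X chromosome lay 2.80, 2.70, 7.55 and 6.80% of them, against 6.52% of the sequence compared. By both measures replicates 3 and 4 were nearer to random placement than replicates 1 and 2. What set these lists apart stays open: depth, the amount of DNA and differences between animals are not known from peak lists, and no biological explanation was tested.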

How the results depend on the processing

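The alternatives that require peaks in all of the other 3 replicates, the nearest gene end, the background of genes with peaks in all 3 Dam-only replicates, leaving out Chd8 and leaving out the 2 longest CHD8-Dam lists were chosen after seeing the data. Regions with a peak in all 4 CHD8-Dam replicates numbered 3928, 1960 when peaks had to cover at least 50% of the region, 2029 with -log10 q of at least 5, and 3933 to 5926 when 1 replicate was left out (all other 3 required). The depleted lists, 5 as reported, numbered 2 to 5 when 1 replicate was left out in this way, where fewer genes were bound. With a peak required in all 3 Dam-only replicates, the Dam-only lists above other genes fell from 16 to 5 and those below rose from 1 to 2; the cause was not tested. For single lists, alternatives that change no bound gene at all are not counted here, and neither is leaving out Chd8 for lists without it. Alternatives that change only genes outside a list are counted. Of 182 counted alternatives for lists called with merged CHD8-Dam regions 139 stayed past the threshold, 40 did not and 3 changed sign. Of 60 for lists not called 7 newly passed. Among genes with peaks in all 3 Dam-only replicates 1 list passed on the high side and 3 on the low side, where at most 20 genes per list were left; the p53 pathway (log2 odds ratio -0.10), synaptic genes (-0.17) and the receptors (1.69, 1 gene) changed sign without passing the test, and the cause was not tested. With peaks in all 3 Dam-only replicates, 11 of 17 Dam-only calls ended and 1 was added. The gene-end share of merged regions was 62.6 to 76.7% under all alternatives run. The planned requirement of a peak in at least 3 replicates, and of 2 of the other 3 when 1 is left out, removes no region by construction, and the group difference could pass its exact test in no setting, so these say nothing about stability. Same-numbered replicates were not paired by their values (correlations over genes of -0.01, 0.04 and -0.03); taken as a block, 3 pairs gave a group difference of 20.0 points (exact permutation p = 0.5), and without the 2 longest CHD8-Dam lists it was 33.4. Motifs, GATC-matched placements and the CpG-rich background were not run, for want of a genome sequence here. Depth is unknown, so its limits are too.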

Other observations

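Tests chosen after their results were seen are the comparison of regions inside genes, the edge comparisons and the count of stronger peaks at Chd8, and, for the depleted lists, the odds ratio limits as a test of closed chromatin and the comparison by Dam-only fold; the list tests among genes with a merged Dam-only peak were planned.

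Away from gene ends, CHD8-Dam regions gathered inside genes of neurons and chromatin regulators. A merged region inside the gene and more than 2 kb from any end was present in 742 genes (3.43%). Against 10000 random lists of genes of similar length, 6 of 24 lists had more such genes after adjustment and 0 had fewer. Pan-neuronal genes had 12 of 35 (4.24 times the length-matched mean, two-sided permutation p = 0.0024 after adjustment), with 6 regions in Myt1l, a neuronal zinc finger gene, and 3 each in Rbfox2 and Dpysl3. Chromatin regulators had 12 of 58 (3.40 times, adjusted permutation p = 0.0024), including Kdm6b, Smarca2 and Chd2 with 2 regions each. Upper-layer neurons had 9 of 22 (3.74 times, adjusted permutation p = 0.0048), with 6 regions in Mef2c and 4 in Lhx2, and deep-layer neurons 7 of 20 (3.17 times, adjusted permutation p = 0.018), with 3 each in Sox5 and Tbr1. Autism risk genes had 15 of 54 (2.29 times, adjusted permutation p = 0.0072), with 6 regions in Tcf4, and synaptic genes 15 of 42 (1.95 times, adjusted permutation p = 0.034), with 3 regions in Dlg4. Chd8 itself counts in the autism and chromatin lists. Radial glia genes had the highest ratio (4 of 30, 4.44 times) but did not pass (adjusted permutation p = 0.064). Neither did astrocyte genes (4 of 24, 3.19 times, adjusted permutation p = 0.12). The lists were matched for length only and were not compared with Dam-only peaks inside genes, so accessible chromatin was not taken into account. RNA processing, ribosomal protein and respiratory chain genes, bound often at their ends, had 0 such genes, where 0.953, 0.0909 and 0.546 were the length-matched means.

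The number of genes with 5 or more regions was not above placement, and no single gene was tested. Zeb2, a transcription factor gene, had 11 regions and Gpm6a and Myt1l 8 each, and 24 genes had 5 or more, against a mean of 21.6 and a highest value of 31 over 100 placements.

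Inside Chd8, 5 narrow merged regions had a median edge SD between replicates of 13.3 bp, and 0 of 5 lay in merged Dam-only peaks. The median edge SD was 46.3 bp for the 97 regions elsewhere of at most 394 bp, the widest of the 5. Width was not matched below this limit. The edges argue against methylation as at other narrow regions, since a share of 0.00050 of 10000 random sets of these had edges as close. For open chromatin marked by Dam alone, the binomial probability was 0.00275 at the 69.3% of other regions. That share cannot decide, because most other regions lie at gene ends. Of peaks away from gene ends, 41.0, 42.2, 2.81 and 5.43% lay in merged Dam-only peaks in replicates 1 to 4. Plasmid DNA carrying the coding sequence may be the source, but both bounds set for it were crossed: over the 4 lists 0.161, 0.376, 6.68 and 15.3% of 5583 genes of similar length had as many peaks as Chd8, where under 1% in each list was required, and at -log10 q of at least 5 the shares were 0.161, 0.179, 6.13 and 2.72%, where at most 1 list was allowed 1% or more. Only after both values were seen were these bounds judged wrong, because plasmid reads add peaks to Chd8 and set no limit on other genes; they forbid only a list in which Chd8 holds no more peaks than the median such gene, and it held 10, 14, 6 and 10 against 0, 1, 1 and 5, so plasmid DNA stays open, neither shown nor excluded, and exon positions were not used here. The region over the higher end of Chd8 had an edge SD of 128 bp, at percentile 47.4 of regions of like width. This does not decide on plasmid DNA there, since no value here shows that plasmid reads give close edges.

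The 5 lists depleted against all other genes, GABAergic interneurons, the oligodendrocyte lineage, erythroid cells, Hox genes and olfactory and vomeronasal receptors, had merged CHD8-Dam regions at 2 of the 92 members with a merged Dam-only peak (2.17%, exact 95% interval 0.264 to 7.63%), against 4188 of 12109 other genes with one (34.6%). Closed chromatin, without methylation by Dam alone, is argued against as the whole cause for GABAergic (1 of 25 bound), oligodendrocyte (0 of 16) and Hox genes (0 of 34). Among genes that Dam alone marks, the upper 95% limits of their odds ratios were 0.488, 0.495 and 0.218 (Fisher's exact test, adjusted p of 0.0023, 0.0060 and 1.4e-05). These limits take genes as independent, which the clustered Hox genes are not, so theirs may be too narrow. A Dam-only peak at either end counted, so a gene closed at its other end can count as marked. The choice of lists fixed that few or none were bound, but not how many of them Dam alone marks. Closed chromatin stays open for erythroid genes (0 of 7, limit 1.33) and for the receptors (1 of 10, limit 1.53), of which 0.685% had a merged Dam-only peak. A Dam-only signal too strong to be exceeded is argued against by values that the choice of lists did not fix. The median merged Dam-only fold was 3.37 at the 92 members and 3.64 at the 12109 other genes. Of other genes with equally strong Dam-only peaks 31.8% were bound. The bound share of other genes was 28.3% in the lowest and 50.8% in the highest of 10 equal groups by Dam-only fold. The low share of the lists themselves was fixed by their choice and adds nothing here. In the CHD8-Dam replicates' own lists the log2 odds ratios were -0.87 ± 0.75 for GABAergic, -2.35 ± 0.61 for oligodendrocyte, -1.62 ± 0.51 for erythroid and -4.32 ± 4.13 for receptor genes (n = 4). For the receptors they were -8.58, -7.15, -0.63 and -0.93 in replicates 1 to 4. For all 5 lists they were below 0 in 4 of 4. The merged regions rest on these same replicates, and the microglial and endothelial lists, which were not called, were also below 0 in 4 of 4. That CHD8 may rarely visit GABAergic, oligodendrocyte and Hox genes, if these are silent in the electroporated lineage, is a hypothesis. Expression, CpG content and Polycomb were not tested. The GABAergic and oligodendrocyte calls ended when replicate 1, 2 or 4 was left out and a peak required in each of the other 3. They did not end when replicate 3 was left out in this way.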
